A study of Homo sapiens with 6 samples.

How the data were processed

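RNA sequencing was done on MCF10A cells, an immortalised, non-tumorigenic human breast epithelial line. Per the labels, all 6 samples had received doxycycline for 3 days. Of these, 3 were controls named SCRin with a wild-type genotype and 3 had the genotype α-/-;βin (called PI5P4K-depleted cells here). The labels do not expand SCR, in, α or β. α and β were read as the α and β PI5P4K enzymes, encoded by PIP4K2A and PIP4K2B, because the series title names PI5P4K. Per the labels' protocols, RNA was extracted with a Directzol kit, libraries were prepared from equal amounts of total RNA with Illumina TruSeq reagents and sequenced on a NextSeq instrument. Whether the libraries kept strand is not given in the sources used here. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

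The authors deposited a single table of TPM, a measure of transcript abundance scaled to the same total in each sample, for 27914 genes named by symbol, with 1 column per sample. The genome build was hg19, per the submitters' processing notes. The aligner, the quantification program, the annotation and any filter are not given in the sources used here. Each deposited TPM column summed to 1000000. Control columns matched the control samples by name and replicate number. The other columns are headed as the experiment, and were assigned to the PI5P4K-depleted samples as the remaining group, by replicate number. TPM keeps no total depth, so the number of reads per sample is unknown. Among genes under 1 TPM, the most common ratio of a sample's value to that of the first control lay between 0.919 and 1.042. Only a narrow range of ratios was searched, so a large difference in relative depth could have been missed. Between 14738 and 15058 genes had a TPM above 0 in a sample, and between 11859 and 12116 reached 1 TPM. Genes for short RNAs, such as small nucleolar RNAs, took 7.34% to 8.62% of the TPM in a sample. RPL21, a ribosomal protein gene, was listed at 0 in PI5P4K-depleted replicate 3 and at 19.8 to 325 TPM in the controls, so an exact 0 can be a failed estimate. For genes with a 0, the value of each library is given.

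The TPM values were transformed to log2(TPM + 1), which understates the change of genes with low values. Genes with a mean TPM of at least 1 over the 6 samples were tested, which left 12096 genes (43.3%). The groups were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, two-sided. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Higher and lower refer to PI5P4K-depleted cells relative to controls. Targeted genes were also compared by an exact two-sided permutation test of TPM, for which 3 samples against 3 allow no p below 0.1. Values are given as mean ± SD with n = 3 per group, and SE is that of the limma fit.

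A total of 34 gene lists was written from general knowledge, with the design, the tests and most alternatives, before the data were examined. Of these, 30 lists had at least 5 measured members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists. Camera compares the genes of a list with all other genes. An estimated correlation and fry, which tests a list on its own, were alternatives. The per-library mean of a list was also compared by an exact permutation test. Genes were named by a fixed rule. It took the 3 PI5P4K genes and 6 usual YAP and TAZ readouts. It took the 8 highest and the 8 lowest log2 changes among genes past the threshold whose groups did not overlap and whose mean reached 5 TPM in the higher group, leaving out clone, LOC, LINC, microRNA and other short RNA names. For each list it took up to 2 rising and 2 falling members past the threshold, or none or the most highly expressed member. Any other gene is said to be chosen after its values were seen.

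Gene order was taken from the RefSeq annotation of GRCh38.p14, which matched 27010 of the 27914 symbols and 11975 of the 12096 tested genes. It is not the authors' build, so it was used only for names, chromosomes and neighbours, and no coordinates are given. Of the 121 tested genes left without a chromosome, 25 were placed by their exact name in GENCODE v29, as an alternative chosen after the calls had been seen. After the calls had been seen, runs of neighbouring genes with a mean of at least 5 TPM were searched. A stretch was at least 10 genes in a row at which the running median of the log2 change over 15 genes was -0.5 or lower, or 0.5 or higher. The gene order was shuffled 1000 times to give the lengths that arise by chance.

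The gene test was run on simulated data with the means and spreads of this comparison over 12096 genes, 200 of them changed. At a log2 change of 1, 77.4% of changed genes were called, and at a log2 change of 2, 96.8%. False calls made up 6.4% of all calls. In the deposited values, camera was run on random lists of 21 genes, each called at an unadjusted p under 0.05. It called 4.5% of lists with no added shift and 98.5% of those with an added shift of 0.25 on the log2 scale. The written gene lists were called at an adjusted p, a stricter rule, so 98.5% may overstate the power of that test. Random lists lack the correlation between members of real pathways. The stretch search found a run of neighbouring genes planted on chromosome 2 among resampled log2 changes, and no other. Alternatives covered pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, other scalings, limma without a trend or with robust estimates, the replicate number as a block, and leaving out each sample. Tables were prepared with pandas 2.3.3 and plots with matplotlib 3.10.9 under Python 3.11.15.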

Results

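Expression was measured as TPM in 3 control libraries (SCRin control, wild-type) and 3 libraries of PI5P4K-depleted cells (α-/-;βin), all from MCF10A breast epithelial cells given doxycycline for 3 days. PI5P4K enzymes phosphorylate the lipid PI-5-P, and the series title links this lipid to the Hippo pathway, whose transcriptional outputs are the coactivators YAP and TAZ. The comparison asks how the transcriptome of cells labelled α-/-;βin differed from that of controls. No protein was measured, so the enzyme levels themselves are not known from these data. The libraries resembled each other closely, with Spearman correlations across genes of 0.959 to 0.964 among controls, 0.962 to 0.970 among PI5P4K-depleted libraries and 0.944 to 0.965 between the groups.

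Both targeted genes were lower in PI5P4K-depleted cells. PIP4K2A, encoding the α enzyme, measured 20.6 ± 1.02 TPM in controls and 4.20 ± 0.132 TPM in PI5P4K-depleted cells (SD, n = 3), or 20.4% of control. PIP4K2B, encoding the β enzyme, measured 21.8 ± 1.21 and 9.49 ± 1.83 TPM, or 43.6% of control. Their log2 changes were -2.05 (SE 0.10, limma adjusted p = 0.000847) and -1.13 (SE 0.14, adjusted p = 0.00985). PIP4K2C, encoding the remaining enzyme of the family, measured 43.1 ± 4.94 and 34.0 ± 5.70 TPM and did not pass the test (log2 change -0.34, 95% interval -0.69 to 0.01, adjusted p = 0.438). For PIP4K2A and PIP4K2B no library of either group overlapped with the other group, and the exact permutation p was 0.1, the smallest that 3 samples against 3 can give. For PIP4K2C it was 0.2. The PIP4K2B call was lost without control replicate 3, with an adjusted p of 0.0602 (0.00602 to 0.0602 over the alternatives) at a log2 change of -1.14.

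**Figure D1:**
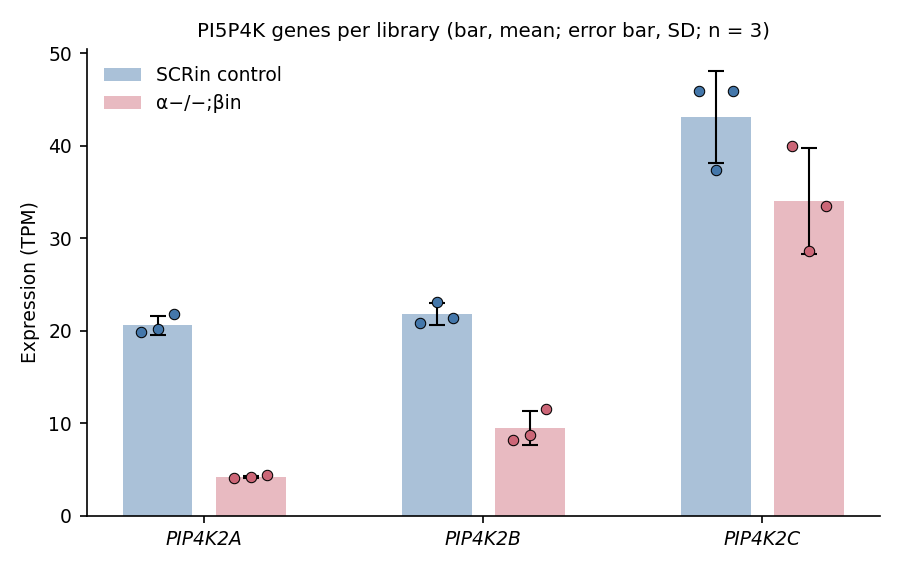
Expression in TPM of the 3 PI5P4K genes in each library (points), with the mean (bar) and SD (error bar) of the 3 control and 3 PI5P4K-depleted libraries. PIP4K2A lay near 4.20 TPM and PIP4K2B near 9.49 TPM in PI5P4K-depleted cells, below every control library, while the PIP4K2C libraries of the groups overlapped.

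Most of the genes that differed were lower in PI5P4K-depleted cells, and most of those were neighbours on chromosomes 7 and 3. Of 12096 tested genes, 265 passed the threshold, 221 of them lower and 44 higher. Along chromosome 7, from FAM20C, the first gene in the order, through CHCHD2, 193 of 196 tested genes had a log2 change below 0. Of these 196 genes, 128 were called lower and 0 higher, with a median log2 change of -0.91 (quartiles -1.07 and -0.77). Along chromosome 3, from SEMA3F through HTD2 and RPP14, which share a start, 66 of 68 tested genes had a change below 0, 36 were called lower and 0 higher, and the median was -0.81 (quartiles -0.95 and -0.71). Among members with at least 20 TPM, the median expression was 51.3% of control on chromosome 7 (119 genes) and 54.9% on chromosome 3 (30 genes).

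The stretches hold genes of unrelated functions. EGFR, the epidermal growth factor receptor, lay in the chromosome 7 stretch and fell from 206 ± 12.3 to 96.0 ± 1.97 TPM (log2 change -1.09, SE 0.08, adjusted p = 0.00308). TWIST1, a mesenchymal transcription factor, fell from 33.4 ± 1.40 to 15.4 ± 1.87 TPM, and TNS3, a focal adhesion protein, from 27.0 ± 2.42 to 11.8 ± 1.14 TPM. In the same stretch and chosen after their values were seen, PPIA, a prolyl isomerase used as a reference gene, fell from 1940 to 1076 TPM and SEC61G, a subunit of the endoplasmic reticulum translocon, from 1978 to 821 TPM. In the chromosome 3 stretch, WNT5A, a Wnt ligand, fell from 10.3 ± 1.67 to 2.62 ± 0.396 TPM (log2 change -1.64, adjusted p = 0.00561). RASSF1, a scaffold protein connected to the Hippo kinases, fell from 16.7 ± 2.71 to 8.31 ± 0.835 TPM. BAP1 and PBRM1, chromatin regulators chosen after their values were seen, fell from 36.4 to 19.2 TPM and from 27.1 to 14.4 TPM.

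Expression returned to control levels next to the stretches. ZNF680, the next gene of at least 5 TPM after CHCHD2, had a log2 change of -0.09 (adjusted p = 0.830), and RBM5, the gene before SEMA3F, had 0.09 (adjusted p = 0.931). PXK, the gene after RPP14, had 0.17. The rest of chromosome 7 had a median of -0.01 over 368 genes, with 0 lower and 1 higher call. The rest of chromosome 3 had a median of -0.03 over 616 genes, with 3 lower calls and 1 higher call. Relative to the mean of the controls, the chromosome 7 stretch stood at -0.04, 0.05 and 0.02 in the control libraries and at -0.98, -0.87 and -0.90 in the PI5P4K-depleted libraries. For chromosome 3 the levels were -0.05, 0.01 and 0.04 against -0.88, -0.85 and -0.80. None of 1000 shuffled gene orders held any stretch. The stretches were found after the calls had been seen.

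**Figure D2:**
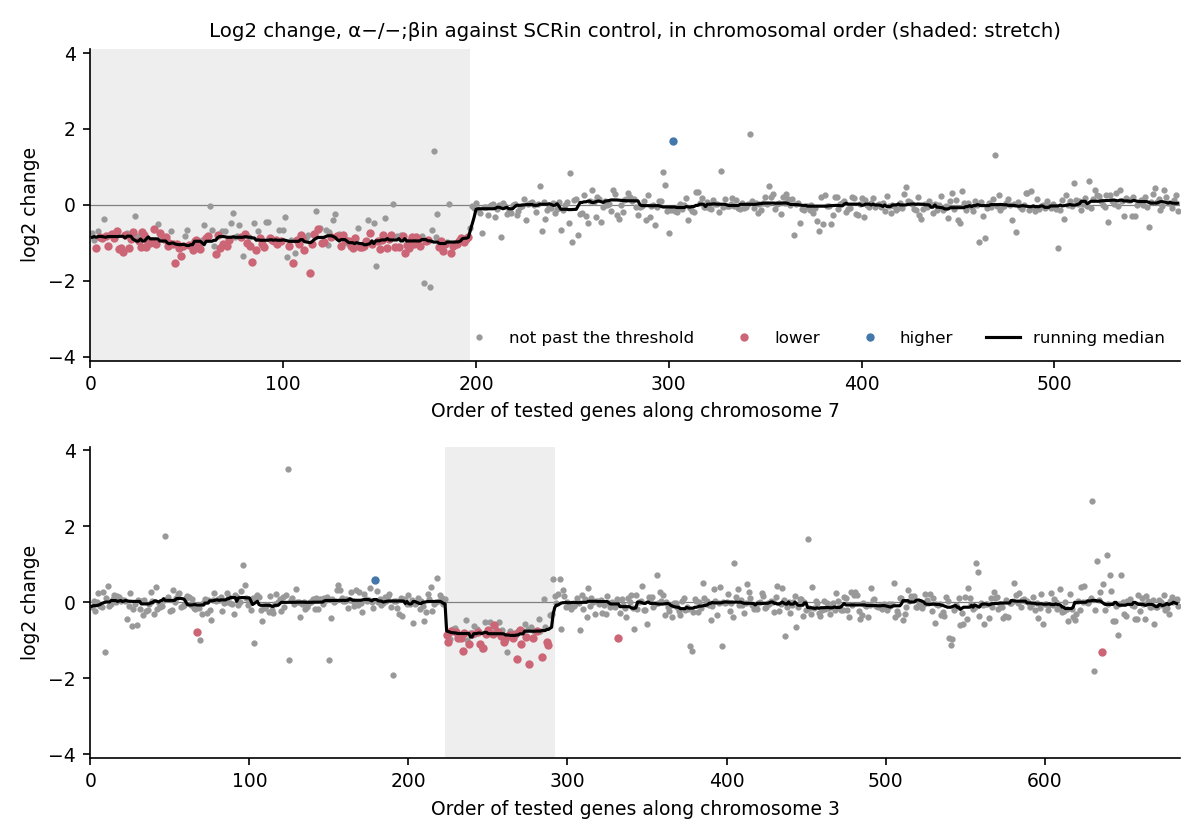
Log2 change of each tested gene (point, PI5P4K-depleted against control cells) in its order along chromosome 7 (top) and chromosome 3 (bottom), with the running median over 15 genes of at least 5 TPM (line) and the stretches shaded. The line lies near -0.91 in the chromosome 7 stretch and near -0.81 in the chromosome 3 stretch, and close to 0 elsewhere on both chromosomes.

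The stretches held 164 of the 265 calls, or 61.9% of all calls and 74.2% of the lower calls. The other 101 genes were 44 higher and 57 lower. The 57 include GARS, NDUFA4 and MPP6, for which the RefSeq order gave no chromosome, while their names in GENCODE v29 place them in the chromosome 7 stretch. With these 3 genes counted there, 98 calls lay outside the stretches, 44 higher and 54 lower. The 54 still include 2 uncharacterised genes whose position is unknown. GARS and MPP6, chosen after their values were seen, fell from 458 to 230 TPM and from 23.0 to 13.2 TPM, and NDUFA4 from 209 to 112 TPM. When the 264 stretch genes were left out of the test, 45 genes passed, all of them among the 101. GARS, NDUFA4 and MPP6 stayed in that test, and NDUFA4 was among the 45. Of the 265 genes, 131 changed by at least 1 on the log2 scale, 110 lower and 21 higher. At an unadjusted p under 0.05 there were 1438 genes, and 2063 genes (17.1%, against 10% by chance) had groups that did not overlap. The number of calls depended on single libraries: 106 genes passed without control replicate 3, 119 without PI5P4K-depleted replicate 3 and 163 without PI5P4K-depleted replicate 1.

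The largest falls were in genes outside the stretches. KDELC2, an endoplasmic reticulum glucosyltransferase, was nearly lost, with 31.4 ± 3.25 TPM in controls and 0.0892 ± 0.0186 TPM in PI5P4K-depleted cells (log2 change -4.89, SE 0.14, adjusted p = 4.56e-05). CDA, the cytidine deaminase of pyrimidine salvage, fell from 62.1 ± 9.07 to 7.25 ± 1.96 TPM (log2 change -2.96, SE 0.20, adjusted p = 0.00308). The long noncoding RNA UCA1 fell from 7.68 ± 3.14 to 0.417 ± 0.231 TPM, and MAP1B, a microtubule-associated protein, from 12.4 ± 2.15 to 1.64 ± 0.809 TPM. On the X chromosome, ARMCX3, a mitochondrial outer membrane protein, fell from 22.8 ± 5.92 to 3.67 ± 1.43 TPM, CLIC2, a chloride intracellular channel protein, from 13.6 ± 3.55 to 1.83 ± 0.477 TPM, and MCF2, a proto-oncogene, from 6.66 ± 2.54 to 0.653 ± 0.263 TPM. ZNF433-AS1, an antisense transcript, measured 5.81, 7.38 and 6.23 TPM in controls, was listed at 0 in PI5P4K-depleted replicate 1 and measured 1.14 and 0.515 TPM in the others.

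The largest rises were also in genes outside the stretches. SRGN, the proteoglycan serglycin, rose from 3.49 ± 0.563 to 58.7 ± 27.9 TPM (log2 change 3.60, SE 0.39, adjusted p = 0.00609). EPCAM, an epithelial adhesion molecule, rose from 10.02 ± 0.791 to 49.5 ± 5.46 TPM (log2 change 2.19, SE 0.12, adjusted p = 0.000847). CHRNA9, a nicotinic acetylcholine receptor subunit, rose from 15.4 ± 2.05 to 67.7 ± 9.76 TPM, and IL1B, the cytokine interleukin-1β, from 40.9 ± 8.96 to 154 ± 12.2 TPM. RAB31, a small GTPase of vesicle traffic, rose from 4.43 ± 2.46 to 17.4 ± 4.76 TPM, CLCA2, a regulator of chloride channels, from 6.83 ± 1.12 to 26.5 ± 12.2 TPM, and TFPI2, a serine protease inhibitor encoded on chromosome 7 outside the stretch, from 9.64 ± 2.61 to 32.9 ± 7.34 TPM. CDC37L1-DT, a divergent noncoding transcript, was listed at 0 in all controls and at 5.25, 12.3 and 17.4 TPM in PI5P4K-depleted libraries. Because strandedness is not given, reads of ZNF433-AS1 and CDC37L1-DT cannot be separated from those of overlapping genes. KDELC2, CDA, MAP1B, ARMCX3, CLIC2, SRGN, CDC37L1-DT, EPCAM, CHRNA9 and IL1B stayed past the threshold under every alternative, while UCA1, ZNF433-AS1, MCF2, RAB31, CLCA2 and TFPI2 missed it under at least 1, with an adjusted p of up to 0.205 for RAB31 without control replicate 3 (0.0031 to 0.205 over its alternatives).

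The usual readouts of YAP and TAZ did not pass the test. CYR61 (CCN1), a matricellular protein, measured 168 ± 63.3 TPM in controls and 193 ± 48.7 TPM in PI5P4K-depleted cells (log2 change 0.24, 95% interval -0.43 to 0.92, adjusted p = 0.830). CTGF (CCN2), its relative, measured 75.1 ± 9.17 and 72.8 ± 6.26 TPM (log2 change -0.04, 95% interval -0.32 to 0.23, adjusted p = 0.948). AXL, a receptor tyrosine kinase, measured 51.8 ± 17.2 and 39.97 ± 13.03 TPM (log2 change -0.37, 95% interval -1.04 to 0.31, adjusted p = 0.701). AXL passed under 1 alternative, with the replicate number as a block (adjusted p = 0.0316, over all alternatives 0.0316 to 0.894). It measured 40.5, 71.6 and 43.3 TPM in control replicates 1 to 3. In PI5P4K-depleted replicates 1 to 3 it measured 29.5, 54.5 and 35.9 TPM, lower at each number. AMOTL2, a junctional scaffold, measured 27.4 ± 2.80 and 28.2 ± 2.87 TPM, and AJUBA, a LIM protein, 39.3 ± 0.715 and 38.0 ± 2.83 TPM. ANKRD1, a nuclear ankyrin repeat protein, averaged 0.307 and 0.278 TPM and lay below the filter.

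Of the 22 genes on the YAP and TAZ target list, 21 were measured, 1 fell, 0 rose and 20 did not pass. F3, the initiator of coagulation known as tissue factor, fell from 608 ± 137 to 310 ± 44.4 TPM (log2 change -0.96, SE 0.18, adjusted p = 0.0490). This call was lost under 12 of 17 alternatives (adjusted p 0.00284 to 0.134), among them each removal of a library. Adjusted over the list alone, 3 genes were lower and 1 was higher. They were F3 with CCDC80, TGFB2 and FOXF2, the last 3 chosen after their values were seen, with log2 changes of -1.14, -0.76 and 0.48. As a set the list did not shift relative to other genes (median log2 change 0.03, mean -0.10, camera adjusted p = 0.998, and adjusted p = 1 with an estimated correlation). Its mean level differed by -0.10 between the groups (exact permutation p = 0.4). Fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.00103. IGFBP3 was the 1 member in a stretch.

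**Figure D3:**
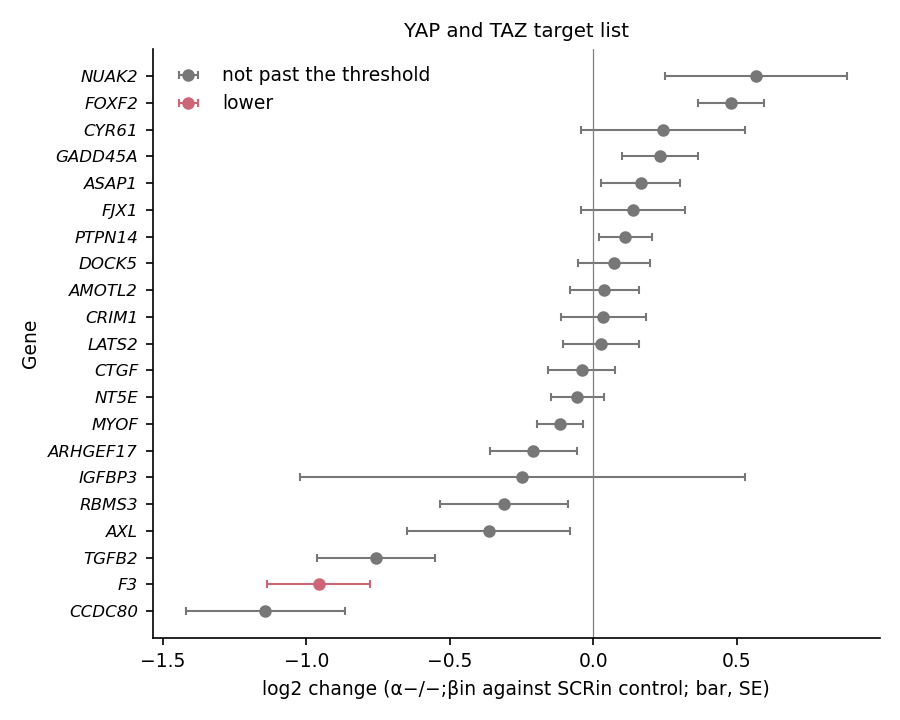
Log2 change (point) and SE (bar) of the 21 measured genes of the YAP and TAZ target list, PI5P4K-depleted against control cells, n = 3 per group. F3 at -0.96 was the 1 member past the threshold over all genes, and the median over members was 0.03.

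Further YAP and TAZ responsive genes and Hippo pathway components also gave few calls. Of 18 measured responsive genes, MYC, a growth-promoting transcription factor, rose from 73.4 ± 2.54 to 112 ± 4.66 TPM (log2 change 0.61, SE 0.08, adjusted p = 0.0110), TNS3 of the chromosome 7 stretch fell, and 16 did not pass. Adjusted over the list alone, MYC was higher and 3 genes were lower, TNS3 with INHBA and FSTL1, the latter pair chosen after their values were seen. The list did not pass camera (median -0.13, adjusted p = 0.385). Its mean level differed by -0.26 (exact permutation p = 0.1, the smallest possible). Without TNS3 and INHBA (log2 change -1.61), which lie in the chromosome 7 stretch, it differed by -0.12 and the groups overlapped (exact permutation p = 0.2). The MYC call was lost without control replicate 3 (adjusted p = 0.0675, over all alternatives 0.00267 to 0.0675) and without PI5P4K-depleted replicate 3. Of 28 Hippo components, RASSF1 of the chromosome 3 stretch fell and 27 did not pass, with the same single call adjusted over the list alone (median -0.03, mean -0.05, camera direction up, adjusted p = 0.998). YAP1 and WWTR1, which encode YAP and TAZ and were chosen after their values were seen, measured 93.4 and 102 TPM and 31.0 and 39.2 TPM in control and PI5P4K-depleted cells. Of 36 phosphoinositide kinases and phosphatases, 0 passed, also adjusted over the list alone (median -0.06, camera adjusted p = 0.685). The most highly expressed, PIP5K1A, a kinase that makes PI-4,5-P2, measured 75.8 ± 5.17 and 68.9 ± 1.35 TPM. Fry's mixed test gave adjusted p of 3.4e-05 for the responsive genes, 0.0188 for the Hippo components and 0.0416 for the phosphoinositide genes. That test included TNS3, INHBA and RASSF1 of the stretches and was not run without them.

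Genes induced by the tumour suppressor p53 were higher as a group with the preset correlation (camera adjusted p = 1.59e-07). The call was lost at an adjusted p = 0.210 with an estimated correlation (0.00701 before adjustment) and by fry's directional test (adjusted p = 0.0616). Fry's mixed test, which gives no direction, had an adjusted p of 0.00154. Of 28 measured members, 24 had a log2 change above 0, with a median of 0.28 and a mean of 0.33. BTG2, an antiproliferative factor, rose from 6.17 ± 1.02 to 13.1 ± 1.43 TPM (log2 change 0.98, SE 0.15, adjusted p = 0.0215), and FDXR, ferredoxin reductase, from 5.25 ± 0.808 to 9.71 ± 0.564 TPM (log2 change 0.78, SE 0.14, adjusted p = 0.0390). Those 2 genes were also the calls adjusted over the list alone, and 26 members did not pass. CDKN1A, the cell cycle inhibitor p21 chosen after its values were seen, measured 120 and 125 TPM (log2 change 0.07). The mean level of the list differed by 0.33 (exact permutation p = 0.1). The BTG2 and FDXR calls were each lost under 8 of 17 alternatives, with adjusted p of 0.0163 to 0.0977 and 0.0199 to 0.184 over the alternatives, most of them with a library left out.

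Basal epithelial markers were higher and mesenchymal genes lower as groups by camera with the preset correlation, but not with an estimated one. Fry's mixed test, which gives no direction, had an adjusted p of 0.000352 for the basal and 0.000929 for the mesenchymal list. Members in the stretches were included in it. The per-library mean levels of the groups overlapped for both lists (differences 0.32 and -0.40, exact permutation p = 0.2 for each). At each replicate number the basal level was higher and the mesenchymal level lower in PI5P4K-depleted cells. The labels only number the replicates and do not say that numbers pair samples. For number 3 the deviations from the group means did not match across the groups (correlation -0.015). The order by number is therefore no test of the difference. Basal levels were -0.03, -0.32 and 0.35 in control replicates 1 to 3 and 0.47, -0.01 and 0.51 in PI5P4K-depleted ones. Mesenchymal levels were -0.18, -0.12 and 0.30 against -0.47, -0.57 and -0.17. Of 18 basal markers, EGFR of the chromosome 7 stretch fell and 17 did not pass over all genes, while adjusted over the list alone 6 were higher and 1 was lower. The 6, chosen after their values were seen, were TP63, DST, KRT5, COL17A1, ITGA6 and SFN, with log2 changes between 0.44 and 0.72. KRT5, a basal keratin, measured 668 and 961 TPM, and TP63, a basal transcription factor, 16.1 and 26.9 TPM. The list had a median of 0.46 (camera adjusted p = 0.00113, and adjusted p = 0.956 with an estimated correlation), and missed the threshold without control replicate 2 (adjusted p = 0.0776). Of 18 mesenchymal genes, TWIST1 of the chromosome 7 stretch fell and 17 did not pass, while adjusted over the list alone 4 were lower and 1 was higher. The list had a median of -0.21 (camera adjusted p = 0.0315, and adjusted p = 0.956 with an estimated correlation), and missed the threshold without control replicate 3 (adjusted p = 0.213), PI5P4K-depleted replicate 1 (0.0518) or replicate 2 (0.118). Of 24 epithelial junction genes, EPCAM rose and 23 did not pass, with 1 higher and 1 lower adjusted over the list alone (median 0.15, camera adjusted p = 0.124, fry's mixed test 5.96e-06). Of 9 luminal markers 0 passed, and KRT7, the most highly expressed, measured 3881 ± 597 and 3566 ± 685 TPM (list median -0.19, camera adjusted p = 0.470).

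A further 5 lists passed camera with the preset correlation and none with an estimated one. Cytosolic ribosomal protein genes had a median of 0.08, with 47 of 52 above 0 (adjusted p = 0.00188, and 0.956 with an estimated correlation). Their 1 call was RPL29 of the chromosome 3 stretch, which fell from 2131 ± 168 to 1291 ± 95.1 TPM. TGF-β response genes had a median of 0.05 (adjusted p = 0.0425, and 0.956 with an estimated correlation), and LTBP1, which binds latent TGF-β, rose from 88.3 ± 0.729 to 123 ± 8.92 TPM (log2 change 0.47, adjusted p = 0.0414). Immediate early and MAPK feedback genes had a median of 0.08 (adjusted p = 0.0449, and 0.956 with an estimated correlation) with 0 calls, and 3 higher adjusted over the list alone. These were FOS, DUSP6 and ZFP36, chosen after their values were seen. Basement membrane and matrix genes had a median of -0.14 (adjusted p = 0.0425, and 0.956 with an estimated correlation) and interferon response genes a median of -0.18 (adjusted p = 0.0315, and 0.495 with an estimated correlation), each with 0 calls, also adjusted over the list alone. The LTBP1 call was lost under 8 of 17 alternatives (adjusted p 0.0102 to 0.186), including the removal of any library, and each of these 5 lists missed the threshold in 3 of the 6 fits that left out a library. The exact permutation p of their mean levels was 0.5 for the ribosomal and TGF-β lists, 0.4 for immediate early, 0.3 for matrix and 0.1 for interferon genes.

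ACTG1, cytoplasmic γ-actin, rose from 2180 ± 309 to 3593 ± 386 TPM (log2 change 0.72, SE 0.13, adjusted p = 0.0462), also when adjusted over the actomyosin list alone. The list of 34 measured genes did not shift as a set (median -0.06, camera adjusted p = 0.998). ACTB, cytoplasmic β-actin, lies in the chromosome 7 stretch, was chosen after its values were seen and measured 6998 ± 1405 and 4898 ± 858 TPM (log2 change -0.51, adjusted p = 0.317). The actins are near-identical, so the split of their reads is uncertain, and the ACTG1 call was lost under 11 of 17 alternatives (adjusted p 0.0016 to 0.183). Of 22 NF-κB and cytokine genes, IL1B rose and 21 did not pass, with 1 higher and 1 lower adjusted over the list alone (median -0.20, camera adjusted p = 0.986, fry's mixed test 0.000475). Of 15 Notch and Wnt genes, WNT5A of the chromosome 3 stretch fell and 14 did not pass, with 1 higher and 2 lower adjusted over the list alone (median 0.18, camera adjusted p = 0.139, fry's mixed test 8.8e-05). Of 37 oxidative phosphorylation genes, NDUFA4, a respiratory chain subunit placed in the chromosome 7 stretch by its GENCODE name, fell from 209 ± 12.3 to 112 ± 5.38 TPM, the same single call adjusted over the list alone (median 0.02, camera adjusted p = 0.346).

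The remaining tested lists had 0 calls over all genes and did not pass camera. Cell cycle genes had a median of -0.04 over 44 members (adjusted p = 0.831), and PCNA, the replication clamp, measured 428 ± 26.5 and 425 ± 29.1 TPM. NRF2 targets had a median of 0.14 (adjusted p = 0.194) with 2 lower members adjusted over the list alone. They were HMOX1 and TKT, the latter in the chromosome 3 stretch, both chosen after their values were seen. Adjusted over the list alone, 0 genes passed in each of the other lists. Their medians were -0.08 for lysosome and autophagy genes (adjusted p = 0.124, exact permutation p of the mean level 0.1), -0.05 for cholesterol synthesis (0.998), -0.02 for fatty acid synthesis (0.998), 0.03 for glycolysis and hypoxia (0.139) and 0.03 for insulin, AKT and FOXO genes (0.398). Medians were -0.00 for unfolded protein and integrated stress genes (0.758), 0.00 for integrins and focal adhesion (0.396), 0.02 for squamous differentiation (0.758) and 0.07 for replication histones (0.831). Camera's direction was up for cholesterol synthesis, fatty acid synthesis and stress genes, whose medians were below 0, and the means of the integrin (-0.01), histone (-0.04) and stress lists (0.06) had the opposite sign to their medians.

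Markers of other cell types stood low in both groups. Fibroblast markers had a median of 0.0603 TPM in controls and 0.0286 TPM in PI5P4K-depleted cells over all 13, the highest being FBLN1 at 106 and 86.1 TPM, and the 5 measured members did not pass camera (adjusted p = 0.998). Blood cell, endothelial and neuronal markers had fewer than 5 measured members and were not tested as lists. No member passed over all genes, and adjusted over the list alone 1 was lower, the neuronal marker UCHL1, chosen after its values were seen. Their medians over all listed members were at most 0.0323 TPM in either group, with CD68 at 41.4 and 36.8 TPM, KDR at 1.03 and 0.909 TPM and TUBB3 at 111 and 121 TPM as the highest. None of the 13 mitochondrially encoded genes was matched by symbol.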

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

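The removal of the stretch genes, the removal of short RNA genes with rescaling, the counts outside the stretches, the placing of genes by GENCODE name, the level of the responsive genes without stretch members and the stretch medians were chosen after seeing the data. No named gene and no list changed direction past the threshold under any alternative. Of 602 values of 36 named genes, 511 stayed on their side of the threshold, 90 lost the call and 1 gained it. Of 578 values of 29 lists, 505 stayed, 56 lost the call and 17 gained it. The total of 265 genes became 45 without the stretch genes, with 31.1% of calls higher against 16.6% in all genes, and 106 to 219 when each library was left out. Fewer genes with strong change in the test make the adjustment stricter, and fewer samples lower its power. With a library left out, 13 to 30 genes were higher, 91 to 189 were lower, 73 to 127 changed by at least 1 on the log2 scale and 32 to 84 lay outside the stretches. The count outside the stretches was 98 with genes placed by GENCODE name. It fell to 32 without control replicate 3, 37, 55 and 57 without PI5P4K-depleted replicates 3, 1 and 2. With a pseudocount of 5, which shrinks changes of low genes, 63 genes changed by at least 1.

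The 8 other lists past the threshold became 3 with a filter at 5 TPM, 5 with quantile normalization, 5 without a trend and 3 to 8 with a library left out. The causes were not tested. They became 0 with an estimated correlation and 0 with fry's directional test. For the YAP and TAZ target list, fry's mixed test gave an adjusted p of 0.00103. It also brought the further YAP and TAZ responsive genes (3.4e-05), Hippo components (0.0188), phosphoinositide genes (0.0416), epithelial junction (5.96e-06), NF-κB (0.000475) and Notch and Wnt lists (8.8e-05) past the threshold. Stretch members were kept in it: 2 responsive genes, and 1 gene each of the YAP and TAZ target, Hippo, and Notch and Wnt lists. The mixed test was not run without them, so their part in these values is unknown. PIP4K2B had a log2 change of -1.27 to -1.04 with a library left out, and its adjusted p reached 0.0602 without control replicate 3. The chromosome 7 stretch median was -0.77 with a pseudocount of 5. The chromosome 3 stretch median was -0.88 with a pseudocount of 0.1, -0.68 with 5 and -0.87 to -0.78 with a library left out, the lowest without control replicate 1.

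The replicate numbers matched samples across the groups in part. Deviations from the group means correlated at 0.25, 0.27 and -0.015 between samples of the same number, and control replicate 3 correlated best with PI5P4K-depleted replicate 1 (0.053). Control replicate 1 correlated at -0.24 with PI5P4K-depleted replicate 2, and control replicate 2 at -0.29 with PI5P4K-depleted replicate 1. Deviations from a group mean sum to 0, so these correlations are not independent of each other. Replicates 1 and 2 were thus alike by number across the groups, and replicate 3 was not. Whether this alignment arose by chance was not tested. The main fit leaves any variation shared by number in its error. With the number as a replicate block, 881 genes passed (284 higher, 597 lower, or 32.2% higher), including all 265, 212 changed by at least 1 and 665 lay outside the stretches. In that fit 2996 genes had an unadjusted limma p under 0.05, against 1438 in the main fit. The block brought AXL past the threshold (adjusted p = 0.0316). It also brought epithelial junction (0.0319), lysosome (0.0319) and NRF2 lists past it, and the TGF-β and immediate early lists missed it (both 0.0878). The number of reads is unknown, so counting error could not be separated from other spread.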

Other observations

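The genes of this paragraph lie outside the stretches and were chosen after their values were seen. They were picked singly and stand for no group. FAT2, a protocadherin, rose in PI5P4K-depleted cells from 2.74 to 8.70 TPM, DSC3, a desmosomal cadherin, from 16.4 to 28.2 TPM, NECTIN1, a junctional adhesion molecule, from 33.5 to 58.5 TPM, and ITGA4, an integrin subunit, from 4.76 to 9.97 TPM. HAS3, a hyaluronan synthase, rose from 4.05 to 13.1 TPM, and NXN, a thioredoxin-like oxidoreductase, from 7.70 to 20.1 TPM. MAOA, a monoamine oxidase, rose from 8.37 to 27.7 TPM and SULT1E1, a sulfotransferase, from 0.475 to 3.79 TPM. DMKN, a secreted epidermal protein, fell from 256 to 102 TPM, CST6, a protease inhibitor of epithelia, from 24.1 to 5.68 TPM, and MT1F, a metallothionein whose family shares near-identical copies, from 44.4 to 14.2 TPM. The limma adjusted p of these genes lay between 0.00349 for DMKN and 0.0373 for MAOA.

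Tests of scaling, of enzyme loss against the history of the line, of splits for the counts of genes over all genes, and of correlated p53 members were chosen after the result was seen. Values argue against a few technical accounts of the stretches. Under the other scalings no stretch median rose above -0.768. Those scalings act on whole libraries, so they could hardly bring a stretch to the level of other genes. Genes outside the stretches had a median log2 change of -0.01, which argues against a library-wide scaling as the cause. The highest PI5P4K-depleted library stayed 0.749 below the lowest control on the log2 scale, so a single unusual library does not account for the stretches. In 0 of 1000 shuffled gene orders was a stretch as long. Loss of a copy of each stretch is a candidate explanation, since the abundant members sit near 51.3% and 54.9% of control and vary between genes at most 1.39 times as much as genes elsewhere (MAD), but no DNA was measured. Whether the stretches follow from PI5P4K loss or from the history of the line cannot be told apart, because there is 1 line of this genotype in the data. The same doubt applies to every difference between the groups, inside and outside the stretches.

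The p53 target list was higher with the preset correlation (adjusted p 1.59e-07). The call was lost with an estimated correlation (adjusted p 0.21, unadjusted p 0.00701) and with fry's directional test (adjusted p 0.0616). With the preset correlation, a single library does not account for it, since the adjusted p was at most 2.48e-06 with any library left out. The list has 0 members in the stretches, so the adjusted p of 6.77e-08 without the stretch genes tests nothing about them. The estimated correlation between its members was 0.0248, against the preset 0.01. The interferon list had an estimated correlation of -0.00308, below the preset. Its unadjusted camera p still rose from 0.00522 to 0.033. A rise in p under the estimated setting therefore does not show that members vary together. The adjusted p of 0.21 cannot decide that question for the p53 list, which stays open. The real split gave a camera p of 5.31e-09 and the best other split 4.95e-05, which makes 1 of 10 splits as small.

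The 6 samples can be split into groups of 3 in 10 ways, too few for a share under 0.05. For each count, 1 of 10 splits, the real one, gave as many genes. The real split called 265 genes and the highest of the others 4. For higher genes the counts were 44 and 2, for lower genes 221 and 2, for log2 changes of at least 1 131 and 4, and outside the stretches 101 and 4. Gene lists behaved otherwise: 6 of 10 splits, the real one included, called at least 8 lists, and the highest called 17. Every mixed split with at least 8 lists put both samples of a replicate number on the same side, so variation shared by number may enter those counts. The mixed splits that kept the samples of each number apart called 1, 1 and 3 lists. This sorting was made after the counts were seen. The 6 of 10 splits therefore cannot tell how often the real number of list calls arises without a group difference.

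Among windows of 25 neighbouring genes, the 5 highest medians were in adjoining windows at the end of chromosome 8, from FAM92A to MAF1 and around MYC. In gene order they were 0.118, 0.139, 0.202, 0.132 and 0.174, all below the limit of 0.5 for a stretch, and their cause was not tested.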
